A study of Homo sapiens with 24 samples.

How the data were processed

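The series holds 24 two-colour arrays of total RNA from the ABC lymphoma lines TMD8 and HBL1, 12 per line, with 3 FOXP1 shRNAs on 4 days in each. Per the labels, cells carried a bacterial tetracycline repressor and a retroviral, doxycycline-inducible shRNA, either scrambled or against FOXP1 (21 bp stems: number 26 GGCGGTCCAACGGAGAGACGC, number 36 GACCTCGCCCACGCCCAGCAG, number 42 GCAGCAACAGTGGCATCTCAT), and received 5 to 10 ug/mL doxycycline. Per the labels, knockdown RNA was in Cy5 and control RNA in Cy3 on every array, without a dye swap. Each of the 6 slides held the 4 days of one shRNA in one line. All TMD8 arrays were scanned on 1 day and the HBL1 arrays on 2 other days, per the file headers, so line and scan batch coincide.

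Spot intensity and local background per channel came from the deposited scanner files, made by Agilent Feature Extraction 10.1.1.1 for TMD8 and 9.5.3.1 for HBL1, per the file headers. The scanner software's log ratio in those files is a log10 value of its own dye-normalized signals, per the file headers. The deposited value table holds log10 ratios of the same processed signals, as computed from the files: every value lay within 0.0011 of log10 of red over green processed signal. Its column medians ran from -0.046 to 0.023, so no centring between arrays was found in it. Its direction was read from the files and matched by FOXP1, and no property of scale, centring or direction stayed unknown. No deposited file holds log2 values: the log2 ratios were computed here from the deposited intensities.

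Each array carried 45015 spots, of which 1639 were controls and 41000 distinct probes. Between 110 and 906 spots per array were marked as outliers by the scanner software and left out, and up to 25 spots per array were saturated in red. Median spot signal over the arrays ran from 86.9 to 179.3 in green and from 137.4 to 412.8 in red. Spots well above background made up 54.0% to 67.5% (green) and 57.7% to 69.5% (red) in TMD8, and 60.6% to 90.0% and 64.9% to 97.1% in HBL1. The number of arrays limits the precision.

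Intensities were background-corrected with normexp (offset 50) and normalized within each array by loess, with control spots at weight 0 and no step between arrays, in limma 3.58.1 under R 4.3.3. Tables and figures used jsonlite 2.0.0, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Spots of a probe were averaged. Probes were named through RefSeq accessions (23680 probes), current symbols (2802) or synonyms (1128) of a table of GRCh38.p14 names, and 13390 kept only the name in the scanner files. No coordinate was taken from that table; probe positions in the scanner files are on hg18, where the FOXP1 probes lie on chromosome 3 at 71091098 to 71091157 and 71088711 to 71088770. The brightest probe stood for each of 30499 genes or transcripts. A gene was tested when its probe was well above background in either channel on at least 6 of 12 arrays of a line, which left 22172, of which 14113 had a symbol.

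The design, the alternatives, the gene lists and the rule for naming genes were written before the data were examined. For knockdown effects the 4 days of a shRNA were averaged, and the 6 line-by-shRNA values were tested with lmFit and eBayes against 0 in each line, over both lines, and between lines. Slopes per day were tested on all 24 arrays in 8 line-by-day groups. Benjamini-Hochberg adjusted p under 0.05 was called. The 27 lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated, and with fry. The lists of ribosomal proteins, hypoxia response, metallothioneins and immediate early genes were added after results were seen. Their p-values were adjusted over these 4 lists alone, and those of the other lists over the 27. Named genes were FOXP1, then for both lines the 12 largest called changes each way with the same sign in all 6 means, then the 5 largest each way between lines without overlap of their shRNAs, the 6 steepest called slopes each way with the same sign in both lines, and the 5 largest each way per line. Up to 4 members per list with the smallest p were added, with all members of the FOXP and pro-apoptotic lists. Probes without a symbol, immunoglobulin and T cell receptor segments and sex-specific genes were left out of naming. Genes outside the rule are said to be named after their values were seen. Some genes picked by the rule are not reported here. Of 62 named genes with another probe past the filter, 16 had one of opposite sign.

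The same-day control channels of the 3 arrays of a line deviated together (mean r 0.63 in TMD8 and 0.33 in HBL1, against -0.19 and -0.11 between days), as did the knockdown channels (0.53 and 0.28). Shared control RNA or handling common to a day would each give this, and the 2 were not separated. Correlations were set beside simulated groups without effects that share controls.

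The pipeline was tested on simulated data with 200 of 22172 genes changed. At log2 0.25 it recovered 67.0%, 68.5% and 88.5% of them for TMD8, HBL1 and both lines, and 0% of differences between lines. At log2 0.5 it recovered 98.0%, 98.5%, 99.5% and 89.5%, with at most 6.2% false calls. Slopes of 0.2 per day were recovered in 93.0%, 88.0%, 95.0% and 63.5%, and slopes of 0.1 in 20.0%, 21.0%, 66.5% and 0%. A list shifted by -0.10 was recovered with both correlations and no other list was called. The simulated genes varied independently of each other, so this does not show what the estimated correlation recovers among genes that move together. All these rates describe the simulated data only. In the real data the arrays of a line and day varied together. There, other orders of whole days gave up to 1221 slopes over both lines (median 13, real order 1327). The rates of recovery and of false calls, above all for slopes, may therefore not hold for the real data.

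Alternatives were normexp without an offset, the scanner's log ratio, the deposited value table, centring on the array median in place of loess, Aquantile between arrays, no filter, a filter on all 24 arrays (15923 genes), the mean of a gene's probes, eBayes with trend and robust settings, leaving out each shRNA, days 3 and 4 only, day 4 minus day 1, arrays as units with and without slide as a random block, slide or shRNA number as a fixed block, and an estimated correlation between genes. Leaving out the library labelled HBL1 26 day 1, and it with 2 arrays of unusual signal (HBL1 36 day 4 and TMD8 42 day 1), was added after the data were seen. Genomic positions, probes of sex-linked genes and the identity of unnamed transcripts were not analysed.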

Results

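RNA from 2 lymphoma lines of the activated B-cell-like (ABC) subtype, TMD8 and HBL1, was compared on 24 arrays after knockdown of the transcription factor FOXP1. Each line carried 3 FOXP1 shRNAs, numbered 26, 36 and 42, and was sampled on days 1, 2, 3 and 4 of doxycycline, which gave 8 groups of line and day with 3 arrays each. Every array held knockdown RNA in one dye and RNA of the same line and day with a scrambled shRNA in the other, so each value was a log2 ratio of knockdown to control. Between 54.0% and 90.0% of spots per array were well above background for control RNA and between 57.7% and 97.1% for knockdown RNA. After the filter, 22172 genes or transcripts were tested, 14113 of them with a gene symbol. The replicate was the shRNA, with n = 3 per line, and its 4 days were averaged before testing.

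FOXP1, the gene targeted, is a forkhead repressor that is highly expressed in ABC lymphoma. It fell in both lines, to 39.8% of control in TMD8 (log2 -1.33, SD 0.18, n = 3, adjusted p = 0.000567) and to 57.6% in HBL1 (log2 -0.80, SD 0.28, n = 3, adjusted p = 0.0024). Its ratio was below 0 on 12 of 12 TMD8 arrays and on 11 of 12 HBL1 arrays. In TMD8 the log2 ratios on days 1 to 4 were -1.31, -0.99, -1.15 and -1.06 for shRNA 26, then -1.67, -1.37, -1.45 and -1.17 for shRNA 36, and -1.15, -1.49, -1.49 and -1.68 for shRNA 42. In HBL1 they were 0.27, -0.72, -0.89 and -0.54 for shRNA 26, then -0.60, -0.93, -1.25 and -1.21 for shRNA 36, and -0.58, -0.85, -1.15 and -1.09 for shRNA 42. The library labelled HBL1 26 day 1 therefore went against its label, and a second FOXP1 probe also read above 0 there, at 0.13. It was kept, and without it FOXP1 in HBL1 was -0.88 (adjusted p = 0.000646). The second probe gave 45.9% of control in TMD8 and 58.4% in HBL1. The weaker knockdown in HBL1 did not pass as a difference between lines (log2 0.53, adjusted p = 0.15), and neither did a slope over days (log2 -0.10 per day averaged over both lines, adjusted p = 0.217; -0.22 in HBL1, below 0 with all 3 shRNAs, adjusted p = 0.108; 0.014 in TMD8, adjusted p = 0.948, and -0.04 there with the scanner's log ratio). With each array centred on its median in place of loess, FOXP1 in TMD8 was -0.86 (adjusted p = 0.0472), and in HBL1 it was -0.39 and no longer passed (adjusted p = 0.231, range over alternatives 0.000646 to 0.231). The related genes FOXP4 (log2 -0.04, adjusted p = 0.219) and FOXP2 (log2 -0.01, adjusted p = 0.917, not well above background in HBL1) did not pass, and FOXP3 was not measured.

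**Figure D1:**
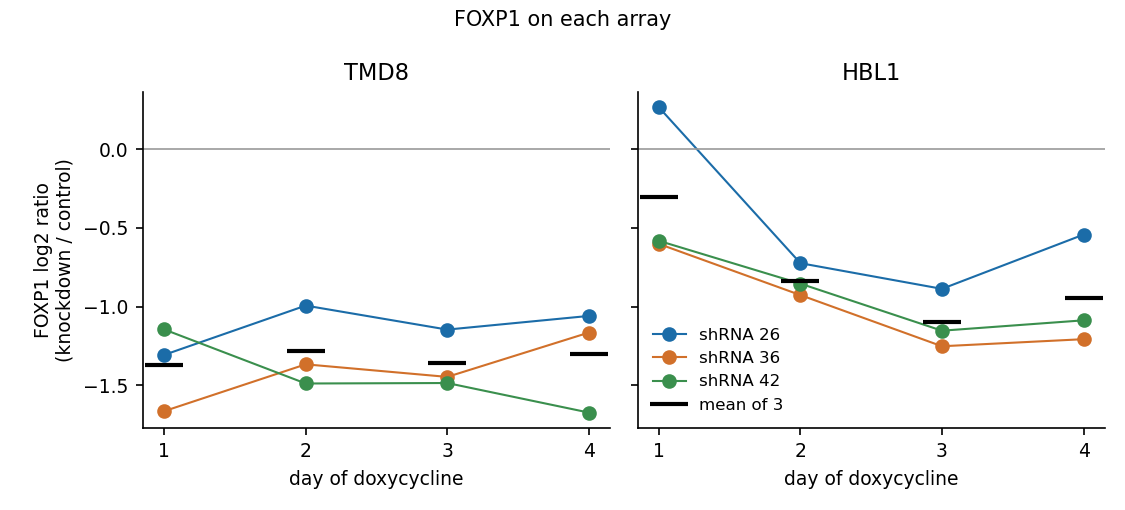
FOXP1 log2 ratio of knockdown to control on each of the 24 arrays, by line, shRNA and day. The library labelled HBL1 26 day 1 lies at 0.27.

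Averaged over both lines, JCHAIN, the joining chain of secreted immunoglobulin, rose 1.82-fold (log2 0.87, SE 0.12, n = 6, adjusted p = 0.00115). The interferon-lambda receptor gene IFNLR1 rose 1.55-fold (log2 0.63, SE 0.06, adjusted p = 0.000278) and the collagen gene COL9A3 rose 1.5-fold (log2 0.58, SE 0.12, adjusted p = 0.00824). Among the falls after FOXP1, the L-amino-acid oxidase IL4I1 fell to 0.64-fold (log2 -0.64, SE 0.09, adjusted p = 0.00135), the lactate exporter SLC16A3 to 0.651-fold (log2 -0.62, SE 0.08, adjusted p = 0.00116) and the glycolytic regulator PFKFB4 to 0.691-fold (log2 -0.53, SE 0.12, adjusted p = 0.00933). The methyltransferase gene COMTD1 fell to 0.67-fold (log2 -0.58, SE 0.05, adjusted p = 0.000213), the replication-licensing factor CDT1 to 0.724-fold (log2 -0.47, SE 0.04, adjusted p = 0.000205), the telomerase gene TERT to 0.732-fold (log2 -0.45, SE 0.02, adjusted p = 0.000111) and the lipoprotein receptor SCARB1 to 0.739-fold (log2 -0.44, SE 0.03, adjusted p = 0.000142). APH1A (log2 -0.54), RAB33A (log2 -0.52), TOX2 (log2 -0.49) and TSR2 (log2 -0.49) completed the lower group. JCHAIN, COL9A3 and IFNLR1 were higher in each of the 6 line-by-shRNA means. Tested by line, IFNLR1 passed in both. JCHAIN passed in HBL1 (log2 1.32, adjusted p = 0.00248) and not in TMD8 (log2 0.42, adjusted p = 0.116). COL9A3 likewise passed in HBL1 (log2 0.87, adjusted p = 0.013) and not in TMD8 (log2 0.29, adjusted p = 0.303). Yet JCHAIN read -0.37, COL9A3 -0.12 and IFNLR1 -0.04 in the library labelled HBL1 26 day 1. With median centring the falls of IL4I1 (log2 -0.29), COMTD1 (log2 -0.23), APH1A (log2 -0.25), TOX2 (log2 -0.10), TSR2 (log2 -0.23), CDT1 (log2 -0.10), TERT (log2 -0.14) and SCARB1 (log2 -0.02) no longer passed, and that of PFKFB4 did not on days 3 and 4 alone (log2 -0.37). A second probe did not follow the main one for SLC16A3 (log2 0.0009) or IFNLR1 (log2 0.07).

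The other 8 named risers of both lines were housekeeping genes of translation and polyamine control: RPL13A (log2 0.69), RPS27 (log2 0.68), OAZ1 (log2 0.67), RPS28 (log2 0.66), EEF1A1 (log2 0.66), RPL28 (log2 0.63), RPL7A (log2 0.62) and RPL23 (log2 0.59). All 8 belonged to the 166 brightest genes on the array, of which 156 were called higher and 0 lower by limma. The rise went with brightness: ribosomal protein genes, a list added after the result was seen, had a median of 0.35, and the 100 brightest other genes had a median of 0.30, with 99 above 0. RPS27 was saturated on 3 arrays and RPS28 on 1. Other probes of EEF1A1, RPL28, RPL7A, RPL23 and RPS28 read lower than the main ones, from -0.0018 to 0.33. These 8 are set apart here because their rise went with brightness. The next risers below that brightness were also named after the result was seen. They were the Fc receptor-like gene FCRL3 (log2 0.56, adjusted p = 0.00123), the interferon-inducible TRIM22 (log2 0.56, adjusted p = 0.000118), C12orf42 (log2 0.54, and 1.43 with the scanner's log ratio) and SEL1L3 (log2 0.53). After them came the chemokine-signal regulator RGS1 (log2 0.50, adjusted p = 0.000251), RPL6 (log2 0.50), RASSF6 (log2 0.49, and 1.05 with the scanner's log ratio), ATOSA (log2 0.49) and DHTKD1 (log2 0.49). RPL6 is itself a ribosomal protein gene (log2 0.35 with the scanner's log ratio and 1.06 with median centring), so it may belong with the 8. The ratio also varied with brightness below the 166 brightest genes, with a median of -0.0555 in the group at brightness 13.87.

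**Figure D2:**
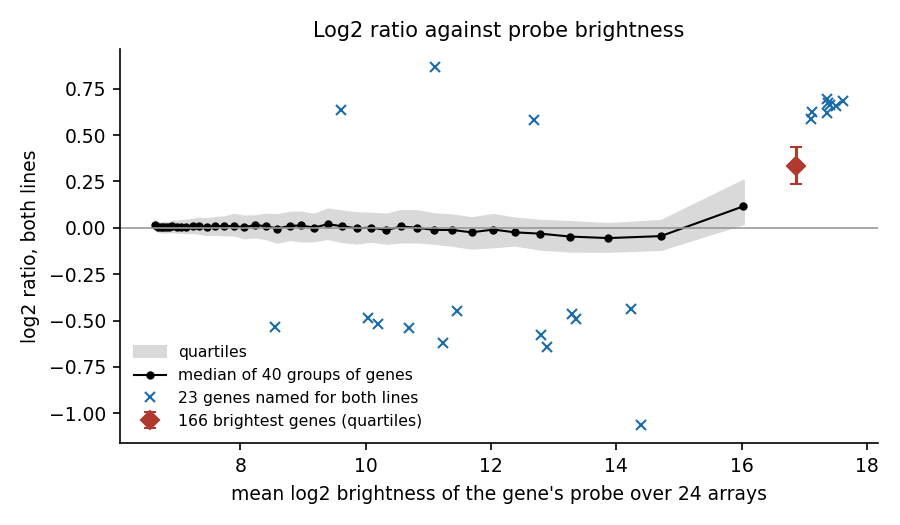
Median and quartiles of the both-lines log2 ratio in 40 groups of genes ordered by brightness, with the 166 brightest genes apart and the 23 named genes marked. The 166 brightest genes had a median of 0.335.

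In the test over both lines 6819 of 22172 genes passed (30.8%, 3472 higher and 3347 lower), and most of these effects were small. Their median absolute log2 was 0.145, 43 passed log2 0.5 (1.41-fold), and FOXP1 alone passed 2-fold. The share of higher genes was 50.9%, and 72.2% with median centring, which shifted the median of all genes to 0.14 from 0.0026. Median centring subtracts a constant per array and leaves any trend of the ratio with brightness in place. With it the 100 brightest other genes had a median of 0.866, against 0.297 with loess. Sign changes with median centring below are therefore not particular to the genes or lists named. Without the 166 brightest genes 6663 of 22006 passed (3316 higher, 3347 lower). Fewer genes were called when shRNA 42 of HBL1 was left out (4392), and more with median centring (11190). These p-values measure only the spread between the shRNAs of this series, which may be technical, and the 3 arrays of a line and day varied together in both dyes. All arrays carried knockdown in the same dye, so a gene-specific dye effect stays in every ratio tested against 0.

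**Figure D3:**
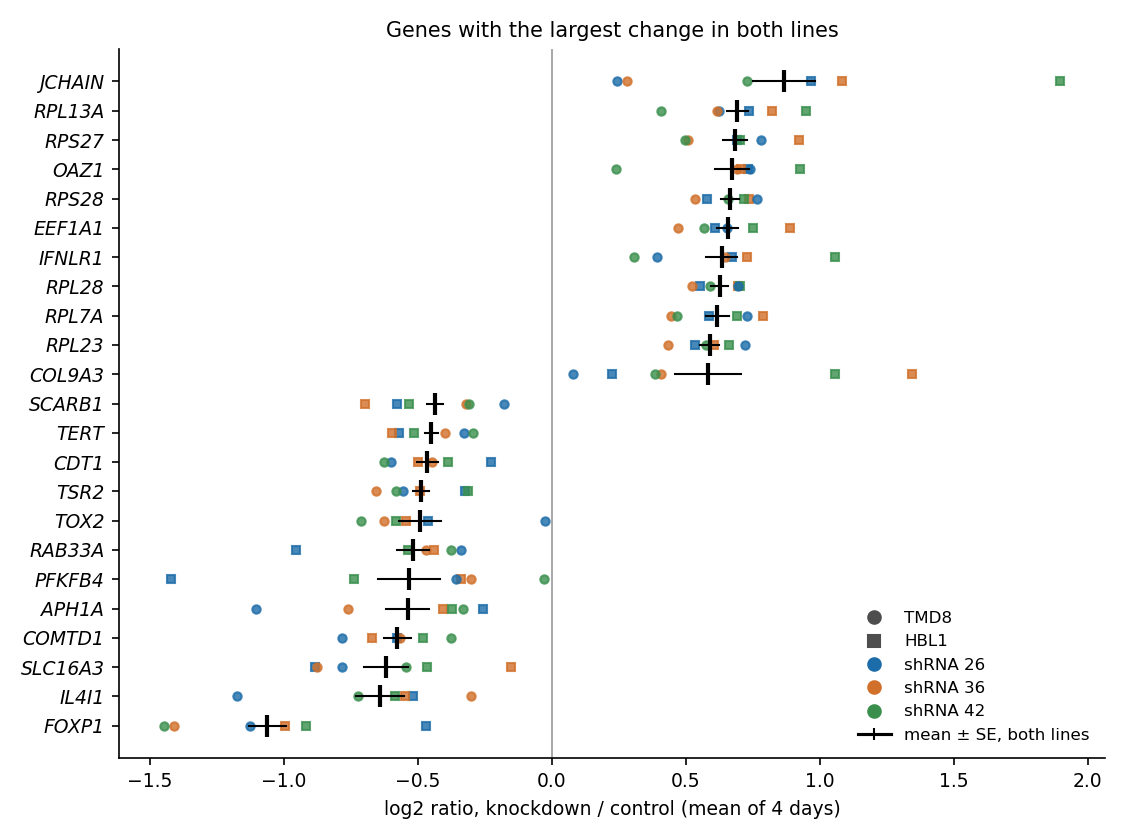
Log2 ratio of the 23 genes named first for both lines, as 6 line-by-shRNA means with the mean and standard error. JCHAIN is at 0.87 and FOXP1 at -1.06.

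Of interferon-stimulated genes 24 of 39 were higher, 2 lower and 13 did not pass (median log2 0.299; 30 called when adjusted over the list alone). The antiviral restriction factor TRIM22 rose by 0.56, the STAT partner IRF9 by 0.42 (adjusted p = 0.000192), and the oligoadenylate synthetases OAS2 and OAS1 by 0.42 and 0.22, while a second IRF9 probe read -0.03. The competitive camera test asks whether list members shift more than other genes. It called the list with a preset correlation (adjusted p = 1.44e-07). It did not with the correlation between its genes estimated from the data (adjusted p = 0.962 with an estimated correlation). The self-contained test fry did not call a common direction either (adjusted p = 0.0823), though it called moves either way (adjusted p = 0.00193). The genes of this list moved together from shRNA to shRNA (estimated correlation 0.668). The list's median was 0.36, 0.57 and 0.23 for shRNAs 26, 36 and 42 in TMD8, and 0.41, -0.00057 and 0.015 in HBL1, so in HBL1 the list's median rose with shRNA 26 alone. In HBL1 6 of 39 list genes were higher and 2 lower. The genes just named rose with all 3 shRNAs there, TRIM22 by 0.55 to 0.62, IRF9 by 0.26 to 0.44, OAS1 by 0.20 to 0.26 and OAS2 by 0.10 to 0.50. They were picked for the smallest p over these same means, so their likeness across shRNAs says nothing about the list. The slide of shRNA 26 includes the library labelled HBL1 26 day 1, where the list's median was 0.18.

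Of genes of the germinal-centre B-cell-like (GCB) signature, the class to which ABC lymphoma is contrasted, 13 of 27 were higher, 0 lower and 14 did not pass (median log2 0.117; 14 called over the list alone). The signalling adaptor STAP1 (log2 0.42, SE 0.03, adjusted p = 0.000204), the formin DAAM1 (log2 0.38), the germinal-centre gene IRAG2 (log2 0.42) and the inositol kinase ITPKB (log2 0.18) were all higher. The list was called with the preset correlation (adjusted p = 8.89e-05; adjusted p = 0.786 with an estimated correlation), and its median was above 0 on all 6 slides. The ABC signature itself gave a mixed picture, with 7 of 29 higher, 12 lower and 10 not passing (20 over the list alone; median log2 -0.096, and 0.289 with median centring; adjusted p = 0.33). TNFRSF13B fell by 0.34, CFLAR by 0.28 and ARID3A by 0.27, of which CFLAR and ARID3A turned to 0.095 and 0.022 with median centring. The phosphatase PTPN1 rose by 0.27.

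The lists of cholesterol synthesis and of S phase held more falling than rising genes. In the sterol list 13 of 21 fell, 1 rose and 7 did not pass (15 over the list alone; median log2 -0.113, and 0.244 with median centring). MVD fell by 0.32, and MVK by 0.27 and SQLE by 0.23, although MVK and SQLE turned to 0.15 and 0.18 with median centring. In the S-phase list 12 of 28 fell, 3 rose and 13 did not pass (18 over the list alone; median log2 -0.078, and 0.268 with median centring). CDT1 led it, followed by CDC6 (log2 -0.25) and MCM7 (log2 -0.22), and the last 2 turned to 0.067 and 0.25 with median centring. On the library labelled HBL1 26 day 1, where FOXP1 read 0.27, the GCB median was 0.020. The S-phase and cholesterol medians there were -0.19 and -0.095, so both were below 0 where FOXP1 had not fallen. Both lists were called with the preset correlation (cholesterol adjusted p = 0.000137, S phase adjusted p = 0.00555; each adjusted p = 0.786 with an estimated correlation). Of the 27 lists 4 were called by camera with the preset correlation, 0 with an estimated correlation (also 0 at unadjusted p under 0.05). Fry, which asks whether a list's own members shift in a common direction, called 5. They were the ABC, GCB, S-phase and cholesterol lists, and the FOXP list, in which FOXP1 alone passed. Its version that counts moves either way called every list (highest adjusted p = 0.0179, NK markers), so it singled out none. The S-phase camera call was lost with the scanner's log ratio (adjusted p = 0.0946) and the value table (adjusted p = 0.112) and was upward with median centring (adjusted p = 0.0268), where the cholesterol call was lost (adjusted p = 0.0782).

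The remaining lists were not called over both lines, though many of their genes passed. Of all genes tested 30.8% passed too, so counts below that lie near this share are no result about a list. In B-cell receptor signalling 12 of 25 rose and 5 fell (17 over the list alone; median log2 0.022), with INPP5D at 0.22, whose second probe read -0.0011, and PIK3CG at 0.17. Mature B-cell identity had 9 of 31 higher and 4 lower (16; median 0.020, and -0.011 with the scanner's log ratio), including BANK1 (log2 0.29) and POU2F2 (log2 -0.30), and TCF3 at -0.17 (0.29 with median centring). The plasma-cell list had 6 of 24 higher and 5 lower (12; median 0.026), with ZBTB38 at 0.41, SEC61B at 0.32 and DERL3 at -0.26. NF-kB targets had 5 of 32 higher and 8 lower (16; median -0.034, and 0.234 with median centring), with CCL17 at -0.34, IL6 at 0.21 and IER3 at -0.20 (0.019 with median centring). JAK-STAT3 targets had 4 of 18 higher and 3 lower (7; median 0.029), with PIM1 at 0.31 and PIM2 at -0.13 (0.26 with median centring). MHC class II had 5 of 20 higher and 0 lower (3; median 0.032), led by the protease CTSS (log2 0.36, SE 0.02, adjusted p = 0.000118), whose second probe read 0.06, with RFXAP at 0.15. MHC class I had 4 of 19 higher and 6 lower (10; mean 0.0023; median -0.014, and 0.294 with median centring), with HLA-C at 0.31 and TAPBP at 0.19, while the other 3 TAPBP probes read between -0.05 and -0.02 and the other HLA-C probes from -0.27 to 0.27.

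Among genes of cell death, the pro-apoptotic genes linked to FOXP1 had 3 of 7 higher and 0 lower (4 over the list alone; median log2 0.199, adjusted p = 0.229). The inflammasome sensor AIM2 rose by 0.34 (adjusted p = 0.00412), RASSF6 by 0.49 (adjusted p = 0.00637) and BIK by 0.20 (adjusted p = 0.0156), and TP53INP1, TP63, HRK and EAF2 did not pass. The BCL2 family had 3 of 15 higher and 5 lower (9; median -0.040, and 0.231 with median centring), with BCL2 up by 0.19, whose second probe read 0.01, and BAX, BMF and BID down by 0.27, 0.24 and 0.23, all of which turned positive with median centring. p53 targets had 5 of 24 higher and 5 lower (12; median 0.0026, and -0.028 with the scanner's log ratio), with RRM2B at 0.26, FAS at 0.24 and PHLDA3 at -0.22. The migration list had 7 of 22 higher and 7 lower (14; median 0.018), with RGS1 at 0.50, RGS2 at 0.37 and S1PR4 at -0.21, and FOXO targets had 4 of 18 higher and 4 lower (10; median -0.022, and 0.225 with median centring). In the latter SESN1 was at 0.22, CDKN1B at 0.14, whose second probe read -0.01, and KLF2 at -0.33 and S1PR1 at -0.17, and these 2 turned to 0.00027 and 0.11 with median centring.

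For growth and stress, G2/M genes had 3 of 30 higher and 10 lower (22 over the list alone; median log2 -0.0061, and 0.0068 with the scanner's log ratio and 0.321 with median centring), including CCNB1 at 0.17 and AURKB at -0.21 (0.046 with median centring). MYC targets had 7 of 30 higher and 8 lower (19; mean -0.0049; median 0.0029, and -0.044 with the scanner's log ratio), including FBL at 0.25, whose second probe read -0.04, and TCOF1 at -0.30, whose second probe read 0.11. ATF4 and unfolded-protein genes had 4 of 24 higher and 6 lower (13; median -0.081, and 0.232 with median centring; adjusted p = 0.0831). There PHGDH fell by 0.39 and DNAJB9 rose by 0.25, whereas TRIB3 fell by 0.32 and CTH by 0.24 but turned to 0.084 and 0.027 with median centring. The Wnt list had 1 of 17 higher and 1 lower (1; median 0.017, and -0.0048 with the scanner's log ratio), and checkpoints had 3 of 15 higher and 2 lower (7; median 0.030), with CD80 at 0.14. Over both lines camera called no list of markers of other cell types (with median centring all 4 were called lower, adjusted p = 0.00407 to 0.0418). Their counts were T cell 1 higher and 1 lower of 10 (2 over the list alone), myeloid 0 and 1 of 8 (1), NK 1 and 0 of 10 (0), and epithelial 0 and 3 of 10 (3). The FOXP list had 0 of 3 higher and FOXP1 alone lower (1).

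**Figure D4:**
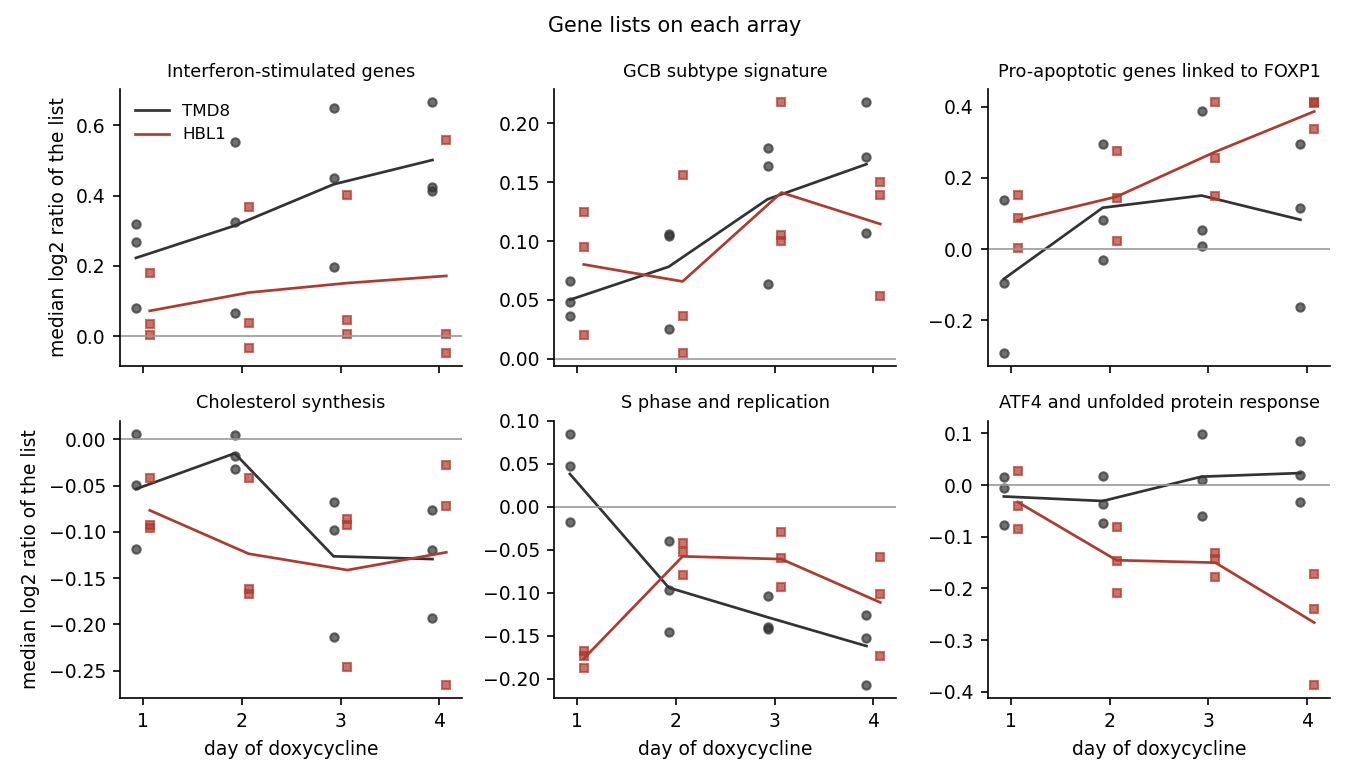
Median log2 ratio of 6 gene lists on each array against day, with line means. On the library labelled HBL1 26 day 1 the interferon-stimulated median was 0.18. The cholesterol and S-phase directions turn positive with median centring, where most list medians read above 0.

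In TMD8 alone the interferon response was larger, with 23 of 39 list genes higher and 1 lower (median log2 0.39, adjusted p = 1.01e-10; adjusted p = 0.841 with an estimated correlation). XAF1 rose by 0.70, IFI27 by 0.69, IFI44 by 0.67 and IFI44L by 0.66, while in HBL1 the same genes read 0.28, -0.02, 0.04 and 0.07. The dystrophin-complex gene SSPN rose 2.06-fold (log2 1.04, SD 0.62, n = 3, adjusted p = 0.00604), and TNNI2 (log2 -0.58), HIRA (log2 -0.56), ADIRF (log2 -0.53) and ITGAX (log2 -0.53) fell. GCB genes (median 0.086, adjusted p = 0.00212), S-phase genes (median -0.074, adjusted p = 0.0242) and cholesterol genes (median -0.073, adjusted p = 0.0242) were called in TMD8, each with adjusted p = 0.841 with an estimated correlation. The S-phase and cholesterol medians in TMD8 turned to 0.348 and 0.324 with median centring. In all, 4197 of 22172 genes passed in TMD8 (18.9%, 2184 higher and 2013 lower), and 2653 without shRNA 36 of that line. The share of higher genes in TMD8 was 52.0%, and 99.6% with median centring.

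Tested in HBL1 alone, SYT17 rose 1.92-fold (log2 0.94, SD 0.43, n = 3, adjusted p = 0.00336), RGS13 by 0.80, FCRL3 by 0.78, the chemokine receptor CXCR4 by 0.74 and RGS1 by 0.73, and RGS1 also passed in TMD8 (log2 0.28, adjusted p = 0.0181). These genes rose despite opposite values in the library labelled HBL1 26 day 1 for FCRL3 (log2 -0.32), RGS13 (log2 -0.37) and CXCR4 (log2 -0.24). DEPP1 (log2 -0.63), RNF183 (log2 -0.57), POFUT4 (log2 -0.50), VEGFA (log2 -0.50) and CCND2 (log2 -0.47) fell. Besides interferon (median 0.145, adjusted p = 0.00415), GCB (median 0.082, adjusted p = 0.000525), S-phase (median -0.091, adjusted p = 0.00107) and cholesterol genes (median -0.112, adjusted p = 1.72e-05), 4 lists were called only here. They were MHC class II (median 0.18, adjusted p = 0.00539), pro-apoptotic genes (median 0.203, 4 of 7 higher, adjusted p = 0.026), ATF4 and unfolded-protein genes (median -0.138, 9 of 24 lower and 1 higher, adjusted p = 6.81e-05) and the FOXP list (adjusted p = 0.0358), which holds the targeted gene and 2 others that did not pass, so its call restates the knockdown. None of the 8 was called otherwise: adjusted p = 0.786 with an estimated correlation for interferon and MHC class II, 0.692 for GCB, 0.772 for pro-apoptotic genes, and 0.52 for the other 4. A rise of 2 of these lists was not confined to HBL1. With shRNA 36 in TMD8 the MHC class II median was 0.19 and the pro-apoptotic median 0.34. With shRNAs 26 and 42 there they were -0.20 and -0.24, and -0.06 and 0.03. The S-phase, cholesterol and ATF4 medians in HBL1 turned to 0.203, 0.153 and 0.072 with median centring. In HBL1 3794 genes passed (17.1%, 1884 higher and 1910 lower), 3874 without the library labelled HBL1 26 day 1, 623 without shRNA 42, and 0 by limma with median centring, where 8290 had an unadjusted p under 0.05.

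The ratios of the lines were alike in direction. Of genes higher in TMD8 870 were also higher in HBL1, against 186 for independent lists, and of those lower 925 were lower in both, against 173, while 11 and 5 went opposite ways. The line means correlated at r = 0.618 (0.0039 in simulated data with shared controls and no effect), a comparison free of shared control RNA and open to the shared dye effect. Within a line the shRNA means correlated at r = 0.542 to 0.732, where simulated controls shared by the 3 arrays of a day gave 0.49. The covariance was 0.0121 against a simulated 0.00255, so part of that agreement may come from shared controls, which could not be split. Between lines r was 0.444 to 0.511 for shRNAs of the same number and 0.42 to 0.49 for others. The library labelled HBL1 26 day 1, with FOXP1 at 0.27, correlated with the TMD8 mean at r = 0.481. The other HBL1 arrays gave 0.325 to 0.544. On that array the likeness between lines was thus present without a fall of FOXP1, so not all of it can be read as a response to the knockdown.

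Some genes differed between lines. The chemokine genes CCL17 and CX3CL1 fell in TMD8 (log2 -0.64 and -0.61) and stayed near 0 in HBL1 (log2 -0.04 and -0.05), a difference of 0.60 (adjusted p = 0.0117) and 0.56 (adjusted p = 0.0176). The death receptor TNFRSF25 rose in TMD8 (log2 0.56) against -0.07 in HBL1 (difference -0.63, adjusted p = 0.00655), while MAB21L1 rose 2.01-fold and LNX1 by 0.52 in TMD8. These 2 genes were not well above background in HBL1, so their tested differences (-1.07 and -0.53) leave open what they did there. The quiescence and homing genes KLF2 and S1PR1 fell only in HBL1 (log2 -0.60 and -0.41; differences -0.55 and -0.48, each adjusted p = 0.0176). The linker histone H1-2 moved in opposite directions, 0.51 in TMD8 and -0.41 in HBL1 (difference -0.91, adjusted p = 0.0176), and the sulfatase SULF2 rose in HBL1 (log2 0.55) against -0.21 in TMD8 (difference 0.76, adjusted p = 0.0296). ATP5MG rose in HBL1 (log2 0.57; difference 0.50, adjusted p = 0.0117). The interleukin-13 receptor IL13RA1 differed by 0.53 (adjusted p = 0.038), and by -0.083 with median centring. AIF1 passed (difference 0.41, and -0.18 with median centring; adjusted p = 0.0176), but was not well above background in HBL1. With the scanner's log ratio the differences of SULF2 (0.77), CCL17 (0.62), CX3CL1 (0.59), ATP5MG (0.27), H1-2 (-0.75) and KLF2 (-0.49) no longer passed (adjusted p = 0.0673, 0.0964, 0.113, 0.194, 0.092 and 0.0968). Other probes of CX3CL1 (log2 -0.02 and -0.07 over both lines), ATP5MG (log2 -0.07) and KLF2 (log2 -0.03) did not follow the main ones (log2 -0.33, 0.32 and -0.33).

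In all 45 genes differed between lines (17 higher and 28 lower in HBL1; 109 without the library labelled HBL1 26 day 1). None differed in limma without shRNA 36 or 42 of HBL1 (3005 and 1999 at unadjusted p under 0.05) or with median centring (1767 at unadjusted p under 0.05), 10 did without shRNA 26 of HBL1, and other settings gave 17 to 104. The share of higher genes among them was 37.8%, and 52.9% from the deposited value table. Between lists, camera placed interferon (difference -0.197, adjusted p = 8.88e-06; adjusted p = 0.788 with an estimated correlation) and ATF4 genes (difference -0.134, adjusted p = 3.33e-07; adjusted p = 0.336 with an estimated correlation) lower in HBL1. MHC class II genes lay higher in HBL1 (difference 0.209, and 0.036 with median centring; adjusted p = 0.0132; adjusted p = 0.788 with an estimated correlation), where HLA-DRA, named after its value was seen, rose by 0.48 against -0.14 in TMD8. The MHC class II median with shRNA 36 in TMD8 was 0.19, however, within the 0.07 to 0.27 of the shRNAs in HBL1. All arrays of a line were scanned on days of their own, with different software versions, so line and batch cannot be told apart here.

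Over the 4 days the Fc receptor-like gene FCRL5 gained most, by 0.43 per day in both lines (SE 0.06, adjusted p = 0.000499), with slopes of 0.24 in TMD8 and 0.61 in HBL1. SLC16A3 gained 0.39 per day (SE 0.06, adjusted p = 0.00218), nearly all of it in TMD8 (0.71 against 0.07), so its low level recovered in that line only. The low level itself rests on the main probe (log2 -0.62 over both lines), since the second probe read 0.0009. JCHAIN gained 0.31 per day (adjusted p = 0.0212), SEL1L3 0.27 (adjusted p = 0.00667), COL9A3 0.28 (adjusted p = 0.0346) and SUSD3 0.26 (adjusted p = 0.0176). In HBL1 the start of these slopes draws on the library labelled HBL1 26 day 1, where FCRL5 read -0.74, JCHAIN -0.37 and SEL1L3 -0.19. Without it the slopes of JCHAIN (0.26, adjusted p = 0.071), COL9A3 (0.24, adjusted p = 0.103) and SUSD3 (0.23, adjusted p = 0.0607) no longer passed, nor did NDUFC1 (-0.14, adjusted p = 0.0617). The immediate early gene EGR1 lost 0.35 per day (SE 0.04, adjusted p = 0.000167), all of it in HBL1 (-0.65 against -0.04), the spindle checkpoint gene MAD2L1 lost 0.19 (adjusted p = 0.00252) and SRSF7 0.16 (adjusted p = 0.000443). CCL17 and CX3CL1 each lost 0.17 per day (adjusted p = 0.000167 and 0.0012), in TMD8 alone, and NDUFC1 lost 0.15 (adjusted p = 0.022).

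The slopes of 9 lists over both lines passed camera with the preset correlation, and 0 with an estimated correlation. Arrays were the units in these tests, with or without slide as a block. All p-values of list slopes therefore leave out variation common to the 3 arrays of a line and day. Interferon genes gained 0.068 per day, and 0.034 with median centring (3 of 39 rising; adjusted p = 3.03e-06; 4.94e-11 with slide as a block; adjusted p = 0.47 with an estimated correlation) and GCB genes 0.033 (2 of 27 rising; adjusted p = 0.00511; 0.000498 with slide as a block; adjusted p = 0.455 with an estimated correlation). The pro-apoptotic genes gained 0.10 per day, and 0.055 with median centring (2 of 7 rising; adjusted p = 0.001; 0.000108 with slide as a block; adjusted p = 0.357 with an estimated correlation). With slide as a block, GCB and pro-apoptotic slopes also passed with an estimated correlation (each adjusted p = 0.0358). MYC targets lost 0.034 (adjusted p = 0.000639; 0.000325 with slide as a block), S-phase genes 0.017 (0.0022; 0.00447), G2/M genes 0.023 (0.00821; 0.0108) and cholesterol genes 0.035 (0.0202; 0.023), with adjusted p = 0.357 with an estimated correlation for MYC and S phase and 0.47 for G2/M and cholesterol. B-cell receptor signalling gained 0.032 (adjusted p = 0.0115; 0.00702 with slide as a block; adjusted p = 0.47 with an estimated correlation) and the BCL2 family 0.025 (adjusted p = 0.0187; 0.0156 with slide as a block; adjusted p = 0.357 with an estimated correlation), and these 2 slopes turned to -0.014 and -0.0026 with median centring.

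With arrays as units, replication genes declined with time in TMD8 and not in HBL1. The p-values here and for ATF4 genes below also leave out variation common to the 3 arrays of a line and day. Orders of whole days could not exclude such variation. Within a line 12 exist, too few for a share under 0.05, and over all genes 10 of 100 gave as many slopes differing between lines. The S-phase list lost 0.066 per day in TMD8, with 5 of 28 genes falling (among them MCM6, MCM4, POLE2 and MCM7, named after their values were seen, with slopes of -0.25, -0.19, -0.16 and -0.15), and passed both ways (adjusted p = 1.38e-07; adjusted p = 0.04 with an estimated correlation). In HBL1 its slope was 0.022 per day, and -0.0145 with median centring, and the difference passed both ways (0.068 per day, adjusted p = 1.56e-07; adjusted p = 0.0242 with an estimated correlation). ATF4 genes declined in HBL1 (-0.068 per day, 2 of 24 falling, adjusted p = 2.36e-07; adjusted p = 0.0146 with an estimated correlation), where the slope was -0.17 for CTH and, named after its value was seen, -0.13 for PSAT1. In TMD8 4 rose, with a list slope of 0.042 per day, and -0.037 with median centring. The difference from TMD8 was -0.10 per day (adjusted p = 3.49e-08; adjusted p = 0.00895 with an estimated correlation).

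By gene, 1327 of 22167 passed the slope test over both lines (729 rising, 598 falling; 2622 with slide as a block, all 1327 among them). The 3 arrays of a line and day varied together in both dyes, so slope p-values leave out variation common to a day. In TMD8 1048 passed (637 rising; 2033 with slide as a block), in HBL1 381 (189 rising; 869 with slide as a block), and 177 slopes differed between lines (56 higher and 121 lower in HBL1; 550 with slide as a block). Leaving out 1 shRNA of a line at a time gave 228 to 1437 slopes over both lines, 334 to 1061 in TMD8, 47 to 373 in HBL1 and 2 to 219 for the difference, lowest without shRNA 26 of HBL1, 36 of TMD8, 26 of HBL1 and 42 of HBL1. Without the library labelled HBL1 26 day 1 these counts were 442 over both lines, 61 in HBL1 and 87 for the difference. With median centring limma called 0 in each, with 888, 330, 1695 and 472 at unadjusted p under 0.05 for both lines, TMD8, HBL1 and the difference. The scanner's log ratio, the value table and normexp without an offset gave 632 to 696 over both lines. The share of rising genes was 54.9% over both lines and 60.8% in TMD8, and 37.2% and 43.3% with the scanner's log ratio. In HBL1 it was 49.6%, and 63.9% with normexp without an offset, and 31.6% of differing slopes were higher in HBL1, and 46.9% with the scanner's log ratio. Slopes of shRNAs in a line correlated at r = 0.164 to 0.555 against 0.48 in simulated data with shared controls, and their covariance was 0.00166 against 0.00186, so shared controls alone could produce that agreement. Between lines the mean slopes correlated at r = 0.236 (-0.015 in simulated data), with 10 rising and 4 falling genes shared against 5.43 and 3.56 for independent lists, while 7 and 2 went opposite ways, against 5.52 and 3.5.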

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

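Some tests below were chosen after the result was seen. They are the test of ribosomal protein genes against equally bright genes and the comparison of interferon medians between shRNAs of a line. The fits without the library labelled HBL1 26 day 1 or without 3 arrays were also chosen then. So were the lists of ribosomal proteins, hypoxia response, metallothioneins and immediate early genes, and with them every test on these lists. The other tests below were set out before.

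A test of the difference between the lines picked out 45 genes for the knockdown effect and 177 for the slope per day. For the knockdown effect these included, as HBL1 minus TMD8, SULF2 (0.76), CCL17 (0.60), CX3CL1 (0.56), ATP5MG (0.50), MAB21L1 (-1.07), H1-2 (-0.91), TNFRSF25 (-0.63), KLF2 (-0.55), LNX1 (-0.53) and S1PR1 (-0.48). IL13RA1 (0.53) and AIF1 (0.41) also passed, and these 2 changed sign with median centring. MAB21L1, LNX1 and AIF1 were not well above background in HBL1, so their differences leave open what they did there. For the slope they included SLC16A3 (-0.64), CCL17 (0.33), CX3CL1 (0.27), MAB21L1 (-0.39), TNFRSF25 (-0.33), EGR1 (-0.61), SRSF7 (0.19), S1PR1 (-0.35) and CTH (-0.30).

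The same test on lists, with the preset correlation, picked out knockdown effects in JAK-STAT3 targets (-0.098), MHC class II (0.209, and 0.036 with median centring), interferon-stimulated genes (-0.197), pro-apoptotic genes (0.183, and 0.023 with median centring), MYC targets (-0.045), ATF4 and unfolded-protein genes (-0.134), epithelial markers (0.055, and -0.013 with median centring), ribosomal proteins (0.130) and metallothioneins (-0.266). With an estimated correlation none of these 9 passed. The pro-apoptotic and MHC class II medians with shRNA 36 in TMD8 were 0.34 and 0.19, above or within the range of the shRNAs in HBL1. It picked out slopes in interferon-stimulated genes (-0.070), FOXO targets (-0.067), S-phase genes (0.068), ATF4 and unfolded-protein genes (-0.103), ribosomal proteins (-0.046, and 0.027 with median centring), hypoxia response (-0.125), metallothioneins (-0.479) and immediate early genes (-0.090). With an estimated correlation the slopes of S-phase (adjusted p = 0.0242), ATF4 (adjusted p = 0.00895), metallothionein (adjusted p = 0.0106) and immediate early genes (adjusted p = 0.0212) still passed and the other 4 did not. Line and scan batch cannot be told apart in any of these differences, and a biological difference between the lines stays open.

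Whether a difference between lines as large could come from other splits was counted on the 6 line-by-shRNA means. 1 of 10 splits into 3 and 3 gave as many genes (real 45, highest other 0), and 10 splits are too few for a share under 0.05. For the slope difference 1 of 100 orders of the days gave as many genes (real 177, highest other 11), which excluded chance order of single arrays. Arrays of a day varied together, however, and when the 3 arrays of a day were kept together 10 of 100 orders gave as many (real 177, highest other 1221, median other 13), so variation common to the 3 arrays of a line and day could produce a count of this size. Orders that turn the days of 1 line around make a slope common to both lines appear as a difference, so part of these counts may hold the slope over both lines.

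The knockdown effects came out as follows. In TMD8 1 of 4 patterns of sign gave as many genes (real 4197, highest other 0) and in HBL1 1 of 4 (real 3794, highest other 0), and 4 are too few for a share under 0.05. Over both lines 1 of 32 patterns of sign gave as many (real 6819, highest other 45), so chance signs of single means were excluded. The means of a line are not independent, since its arrays of a day varied together, and turning whole lines leaves 2 patterns, too few for a share under 0.05. A gene-specific dye effect as the whole cause stayed open. The called genes grew in the direction of their mean on 6 of 6 slides, by 0.0025 to 0.030 per day, but on the slides of shRNA 36 only 51.3% (TMD8) and 51.9% (HBL1) of them grew. The slides of a line share their days, and the mean growth lay within the spread of its 3 slides (95% interval -0.017 to 0.050 in TMD8 and -0.0024 to 0.015 in HBL1).

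For slopes, 1 of 100 free orders of the days gave as many genes in TMD8 (real 1048, highest other 199), in HBL1 (real 381, highest other 12) and over both lines (real 1327, highest other 269), which excluded chance order of single arrays. When the 3 arrays of a day were kept together, 1 of 100 orders gave as many over both lines (real 1327, highest other 1221, median other 13, with none called in 18), so a chance order of whole days seldom gave that count. A steady drift common to the 3 arrays of each day would also put the real order first, so these orders cannot exclude it. In a single line 12 such orders exist, too few for a share under 0.05: 1 of 12 gave as many in TMD8 (real 1048, highest other 534) and 1 of 12 in HBL1 (real 381, highest other 241). Part of the slopes in HBL1 rests on the library labelled HBL1 26 day 1, without which 442 genes passed over both lines. The orders of days were not run again without that library.

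The rise of interferon-stimulated genes was weighed against 3 explanations. A dye effect equal on all arrays as the whole cause was argued against by the shRNAs of HBL1: in 2 of 6 pairs of shRNAs of a line the 4 array medians did not overlap, with 0.18 to 0.557 for shRNA 26 against -0.048 to 0.046 for shRNA 36 and 0.0032 to 0.038 for shRNA 42 on the same days. Single members with like values for all shRNAs are not covered by this. A dye effect that differs between slides stayed open, since the list's median grew on 6 of 6 slides, by 0.0064 to 0.152 per day, but by no more than the spread between the slides of a line (95% interval -0.0023 to 0.216 in TMD8 and -0.093 to 0.173 in HBL1), and 51.3% and 53.8% of its genes grew on the slides of shRNAs 36 and 42 in HBL1. A response to individual shRNAs, which an shRNA without a rise in both lines would have shown, stayed open: 0 shRNAs had a median at or below 0 in both lines, but shRNA 36 had one in HBL1 alone. Loss of FOXP1, which predicts a rise with every shRNA, stayed open too, with 5 of 6 line-by-shRNA medians above 0. In HBL1 these medians were 0.41, -0.00057 and 0.015 for shRNAs 26, 36 and 42, so that of shRNA 42 was hardly a rise. FOXP1 fell least there with shRNA 26 (log2 -0.54 on day 4, against -1.21 and -1.09 for shRNAs 36 and 42). The list in HBL1 thus did not follow the degree of FOXP1 loss. The responses to shRNAs and to loss of FOXP1 cannot be told apart, because double-stranded RNA can itself raise this list and a scrambled shRNA controls for it only in part.

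The rise of ribosomal protein genes had the values that a brightness effect needs: 40.62% of random lists matched on brightness had a lower median, and the matched median was 0.347, as was the list's own. That test drew on the 20 genes nearest in brightness, and with the 50 nearest, a looser match for the brightest genes, 98.2% of lists were lower, so brightness may not account for all of the rise. A constant dye effect as the whole cause also had the values it needs, with a growing median on 2 of 6 slides only. No biological explanation was tested for it.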

How the results depend on the processing

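The fits without the library labelled HBL1 26 day 1, and without it, HBL1 36 day 4 and TMD8 42 day 1, were chosen after the result was seen; all other settings were set out before. The cause of a shift was not tested.

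Normexp without an offset left 24 genes differing between lines and 616, 119, 632 and 66 slopes (TMD8, HBL1, both lines and their difference). The scanner's log ratio left 17 and 439, 159, 696 and 64, and the value table left 104 and 451, 136, 668 and 67. Median centring gave by limma 0 genes in HBL1, 11190 over both lines, 0 differing between lines and 0, 0, 0 and 0 slopes (unadjusted p under 0.05: 8290 in HBL1, 1767 differing, and 330, 1695, 888 and 472 slopes), FOXP1 in HBL1 at -0.39, and 19 lists (15 up, 4 down). The filter on all 24 arrays gave 249 slopes in HBL1, the mean of probes 74 differing genes, and days 3 and 4 only 25. Arrays as units without a block gave 7534, 7933 and 10521 genes. An estimated correlation between genes left 0 lists by camera (0 at unadjusted p under 0.05). Without the library labelled HBL1 26 day 1, 109 genes differed and 61, 442 and 87 slopes passed in HBL1, both lines and their difference. Without the 3 arrays these slopes were 83, 739 and 90.

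As a replicate block, shRNA within line (slide) raised slopes to 2033, 869, 2622 and 550, and slide as a random block (correlation 0.167) gave 5561, 5469 and 8437 genes. In a check of the pairing, arrays of one slide correlated above 0.1 in 25 of 36 pairs (-0.0093 to 0.47). These are not correlations of the log2 ratios themselves, which ran from 0.0369 to 0.766 over all pairs of arrays. The shRNA number as a block gave 52 differing genes, 26 of them shared with the 45. That block was run for this result only. Same-numbered shRNAs, which share a stem sequence, correlated at 0.061, 0.070 and 0.13 between lines in the same check. Their mean log2 ratios themselves correlated at 0.444 to 0.511 between lines.

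Leaving out each shRNA gave 2653 to 3882 genes in TMD8, 623 to 4288 in HBL1, 4392 to 6076 over both lines and 0 to 51 differing. Slopes ran from 334 to 1061, 47 to 373, 228 to 1437 and 2 to 219. FOXP1 ran from -1.43 to -1.27 in TMD8 and from -0.96 to -0.70 in HBL1 (highest adjusted p 0.00397 and 0.0357), and lists from 4 to 5. Over 18 alternatives the adjusted p of FOXP1 ran from 0.000189 to 0.0472 in TMD8 and from 0.000646 to 0.231 in HBL1.

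Reversals of named genes and of list tests, where either value passed, all came with median centring. That setting leaves any trend of the ratio with brightness in place, and most list medians read above 0 with it, such as G2/M at 0.321. Lists of markers of other cell types moved down, such as NK at -0.161. The reversals are thus part of a shift common to many genes. In the knockdown effect over both lines CFLAR read 0.095, ARID3A 0.022, IER3 0.019, PIM2 0.26, NLRC5 0.0076, TCF3 0.29, BAX 0.13, BID 0.23, BMF 0.077, KLF2 0.00027, S1PR1 0.11, AURKB 0.046, CDK1 0.19, BIRC5 0.28, CDC6 0.067, MCM7 0.25, TCOF1 0.12, MRTO4 0.21, TRIB3 0.084, CTH 0.027, ZNRF3 0.069, MVK 0.15, SQLE 0.18, CD40 0.21, KRT8 0.091, APC -0.053 and GNLY -0.21. IL13RA1 read -0.083 as HBL1 minus TMD8. List tests changed direction (list means in brackets) for ABC (0.302), NF-kB (0.263), MHC class I (0.350), p53 (0.266), G2/M (0.333), S phase (0.271), MYC (0.412), cholesterol (0.220), T cell (-0.046) and NK (-0.115), of which MHC class I, p53 and NK kept the sign of the mean. List medians near 0 over both lines also changed sign with the scanner's log ratio, in mature B-cell identity (-0.011), p53 (-0.028), G2/M (0.0068), MYC (-0.044), Wnt (-0.0048), T cell (-0.012) and epithelial markers (0.0039), and without a normexp offset in p53 (-0.016), MYC (-0.0051) and myeloid markers (-0.011).

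Of named genes under all settings, 2872 results stayed as they were, 200 lost and 63 gained the call, and 28 reversed. For lists these were 482, 6, 15 and 10. Over 19 settings GCB was called in 18 (adjusted p 4.41e-06 to 0.786), interferon in 18 (1.08e-10 to 0.962), S phase in 16, 1 of them upward with median centring (8.27e-05 to 0.786), and cholesterol in 17 (5.08e-06 to 0.786). No filter, eBayes with trend and robust settings and day 4 minus day 1 left each count within 1.5 times. Aquantile leaves the log ratios of each array as they are, so it could not move a result, though it is among the settings counted here. Camera took only the trend of that eBayes setting. Signal over background limits genes measured in one line alone.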

Other observations

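The lists of ribosomal proteins, hypoxia response, metallothioneins and immediate early genes, the tests on them, and the genes named from them were chosen after the result was seen. Genes of the hypoxia response, which shift cells to glycolysis, were lower over both lines: 15 of 30 fell, 1 rose and 14 did not pass (22 called over the list alone; median log2 -0.155, and 0.121 with median centring; adjusted p = 7.51e-07; adjusted p = 0.365 with an estimated correlation). SLC16A3 (log2 -0.62, with its second probe at 0.0009), PFKFB4 (log2 -0.53), the enolases ENO2 (log2 -0.42) and ENO1 (log2 -0.28) and ALDOC (log2 -0.31) fell. In TMD8 the list gained 0.120 per day, and 0.042 with median centring (adjusted p = 3.13e-10; adjusted p = 0.0807 with an estimated correlation), with ADM gaining 0.54, CA9 0.38 and ALDOC 0.33 per day, while in HBL1 ALDOC lost 0.28 per day. By shRNA the list's median slope in TMD8 was 0.14 for 26, 0.16 for 36 and 0.011 for 42. The gain was thus hardly present with shRNA 42, where the list's median over the days was -0.015.

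Metallothionein genes, which respond to zinc and other metals, moved apart over the days. Of 11 genes, 9 rose with day in TMD8 (median 0.234 per day, adjusted p = 1.9e-13; adjusted p = 0.0447 with an estimated correlation), led by MT1E (0.45) and MT1L (0.40), and 1 fell in HBL1, MT1B (-0.26; list median -0.189, adjusted p = 6e-07; adjusted p = 0.138 with an estimated correlation). Averaged over days 1 rose and 0 fell, with 0 called over the list alone (median log2 -0.019, and 0.256 with median centring). Immediate early genes fell with day in HBL1, 7 of 35 of them (median -0.088 per day, adjusted p = 6.94e-12; adjusted p = 0.0139 with an estimated correlation). EGR1 led at -0.65, then EGR4 (-0.20), JUN (-0.18) and FOS (-0.17) per day. Over both lines 4 rose and 4 fell (8 over the list alone; median log2 -0.0076, and 0.210 with median centring), with CD69 at 0.46 and JUND at 0.23. Ribosomal protein genes had 68 of 83 higher and 6 lower (77 over the list alone; median log2 0.347, adjusted p = 6.57e-26; adjusted p = 0.309 with an estimated correlation).

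Such swings of metal, hypoxia and immediate early genes, which ran opposite ways or in 1 line, may reflect the state of each day's cultures as much as loss of FOXP1. When whole days were kept together, 12 orders exist within a line, too few to exclude chance, and the highest other order called 534 genes in TMD8 against 1048 for the real order and 241 in HBL1 against 381. These counts cover all genes and not these lists. A separate culture for each shRNA and day would decide it.

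The rise of housekeeping genes may come from the ends of the intensity range. With the scanner's log ratio the ribosomal median was 0.0897 and that of the 100 brightest other genes 0.0771, against 0.347 and 0.297 with normexp and loess, and 40.62% of lists matched on brightness had a lower median. With matching to the 50 nearest genes, where 98.2% of lists lay lower than the ribosomal median, 100% of lists lay lower than the interferon, GCB and pro-apoptotic medians and 0.2% lower than the cholesterol and ABC medians. For S phase the share was 5.4%, so its place among equally bright genes was less clear.

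Markers of T, myeloid, NK and epithelial cells were called in none of the 4 lists by camera (adjusted p = 0.905, 0.918, 0.918 and 0.354), though lower in all 4 with median centring (highest adjusted p = 0.0418), and single members moved both ways, such as LCK (log2 0.16) and KRT8 (log2 -0.17, and 0.091 with median centring). Many were not well above background in 1 of the lines, such as GNLY and EPCAM in TMD8 and CDH1 in HBL1.

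The library labelled HBL1 26 day 1 had FOXP1 at 0.27, FCRL5 at -0.74 and JCHAIN at -0.37. A candidate explanation is slow induction or a wrong label, and neither was tested; without it 109 genes differed between lines in place of 45.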
